A study of Oryza sativa with 12 samples.

How the data were processed

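RNA was measured in the above-ground parts of rice seedlings (Oryza sativa ssp. indica, cultivar 93-11) at the 3-leaf stage. Per the labels' protocols, seedlings about 10 days old, grown in 12 h of light and 12 h of dark at 28 °C, were kept at 28 °C or moved to 13 °C for 4 h before harvest on day 11. Zeitgeber time (ZT) counts the hours from lights-on. Chilling ran from ZT8 to ZT12 or from ZT20 to ZT24, and controls at 28 °C were harvested at the same times. The 4 groups are called NT12, CT12, NT24 and CT24, for normal (NT) or chilling (CT) temperature and the ZT of harvest. Each group had 3 biological repeats of 5 plants, giving 12 libraries made from total RNA with the NEBNext Ultra RNA kit. How RNA was selected before library preparation is not given in the sources used here.

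The authors deposited a table of whole-number counts per gene, with 1 column per library and no normalization, in which column totals differed between libraries. HISAT2 2.0.4 is named in the submitters' processing notes. The counting tool, the genome build, the annotation and any use of strand are not given in the sources used here, so reads shared between near-identical or overlapping genes cannot be assigned with certainty. The table held 40424 identifiers, of which 38714 had the form OsR498G followed by digits and 1710 were numbered like Novel00951. No line lacked an identifier, and 10485 identifiers had no count in any library. What the numbered Novel00951-type identifiers stand for is not given in the sources used here, and such a set may have been built from these libraries. The files do not pair identifiers with names, and 0 of the 40424 matched the reference gene table. For that reason the 13 gene lists and 32 gene families fixed before the data were examined had no matched members and gave no test. They covered the circadian clock, DREB factors, other cold and stress regulators, abscisic acid and dehydrins, heat shock proteins, photosynthesis, chlorophyll synthesis, starch and sucrose, jasmonate, flowering and light signalling, antioxidants, and markers of dividing and root cells.

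Total counts ranged from 42966604 to 52762123 per library. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter (minimum count 10, minimum total 15), which left 24700 genes holding 99.98% of the counts and set 15724 aside. Libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, without a block, leaving 8 residual degrees of freedom. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment within each comparison, and a gene was called when its adjusted p was below 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Where a group has few counts, such an SE is no reliable measure of precision. The 5 comparisons were CT12 against NT12, CT24 against NT24, the difference between those responses (the interaction), NT24 against NT12, and CT24 against CT12. CPM (counts scaled to library size) used the TMM-scaled library sizes, and principal components and correlations used log2 CPM with a prior count of 2.

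The design, the tests, the lists and most alternatives were chosen before the data were examined. The rule for single genes, in the absence of names, took the 2 identifiers that rose most and the 2 that fell most in each comparison. They had to be called, to average at least 5 CPM over all libraries and, in comparisons of 2 groups, to have all 3 libraries of a group above all 3 of the other. For the interaction, every chilled-minus-normal difference between libraries at ZT24 had to lie beyond every such difference at ZT12. Where a group had no count, folds were bounded against a floor of 3 counts over the group's libraries. Where it had 1 to 3 counts, the ratio was given with an exact 95% conditional interval. Floors and intervals cover counting error only, since PCR copies are not independent molecules. Measures of whole libraries were compared by two-sided exact permutation tests, for which 3 libraries against 3 allow no p below 0.1; 28 such comparisons were made. The set of Novel00951-type genes was tested with camera and fry of limma 3.58.1, chosen after the identifiers were seen.

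Libraries of 1 group were compared for duplication. Over genes with at least 20 counts in a pair, the chi-square statistic per gene between libraries of a group lay between 25.5 and 139, far above sampling noise, so each library was counted separately. The common biological coefficient of variation was 0.319.

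The model was tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. For CT12 against NT12, on 24282 genes, 39 of the 2-fold and 63 of the 4-fold changes were recovered, and 5 unchanged genes were called. For CT24 against NT24, on 24285 genes, 26 and 68 were recovered. For the interaction, on 24288 genes, 4 and 44 were recovered. For NT24 against NT12, on 24285 genes, the counts were 20 and 67, and for CT24 against CT12, on 24298 genes, they were 28 and 61. Far fewer genes were changed in the simulation than were called in the data. The Benjamini-Hochberg cutoff was therefore stricter in the simulation, and these shares may understate recovery in the data.

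Alternatives were relative log expression (RLE) and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter (at least 10 counts in all libraries of a group), the replicate number as a block, an adjusted p below 0.01, a test against a fold of 1.5, a fit of only the groups compared, and leaving out each library. Total counts without a composition factor, 1 within-group factor as a covariate, and limma-voom after cyclic loess were added after the data had been seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.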

Results

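Gene expression was measured by RNA sequencing in shoots of indica rice seedlings that had spent 4 h at 28 °C or at 13 °C before harvest at ZT12, the end of the light period, or at ZT24, the end of the dark period. Rice is a warm-season crop in which 13 °C is a chilling but not a freezing temperature. The series title names coordination of the circadian clock with the chilling response as the subject, and the design crossed temperature with time of day. There were 4 groups of 3 libraries: NT12 and CT12 were the normal and chilled seedlings at ZT12, and NT24 and CT24 those at ZT24. Whether the lights followed the growth cycle during chilling is not stated in the labels. Total counts per library averaged 48682645 ± 879477 in NT12, 43405277 ± 753648 in CT12, 46541223 ± 2327776 in NT24 and 50346107 ± 2696055 in CT24 (SD, n = 3). At this depth 3 counts over a group corresponded to between 0.0155 CPM in NT12 and 0.0293 CPM in CT12.

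The 4 groups separated from each other in the main axes of variation. The first principal component held 40.5% of the variance and the second 25.6%. On the first, CT12 libraries lay between -144 and -117, NT12 between -45.5 and -41.2, CT24 between 41.5 and 42.8, and NT24 between 133 and 137. On the second, NT12 lay above 113 and CT24 below -92, with NT24 and CT12 between them. Pearson's r of log2 CPM across genes ranged from 0.934 to 0.978 between libraries of a group and from 0.797 to 0.917 between libraries of different groups. Genes are not independent replicates, so these coefficients describe the libraries only.

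**Figure D1:**
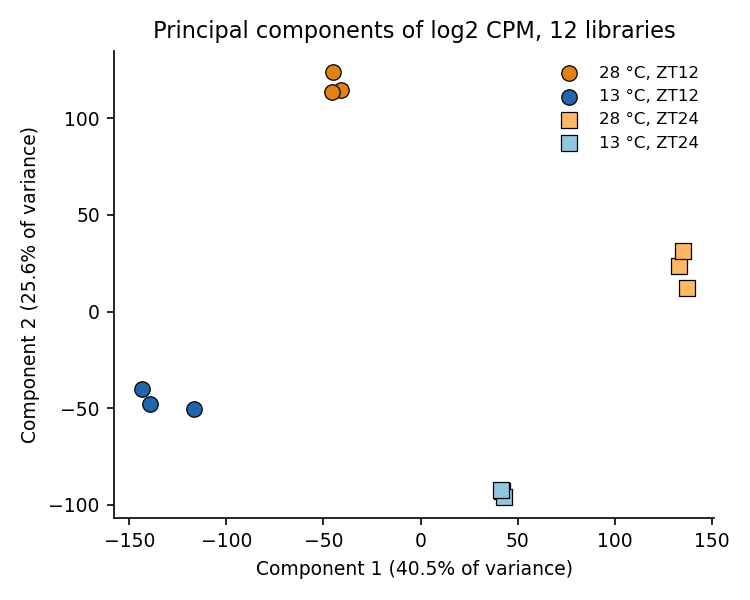
Each point is 1 library, placed by its scores (no unit) on principal components 1 (horizontal, 40.5% of variance) and 2 (vertical, 25.6%) of log2 CPM; colours and shapes mark the 4 groups. The 3 libraries of each group lie together, with CT12 spread from -144 to -117 on component 1.

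Transcripts were more concentrated on abundant genes in some groups than in others. The genes that together held 50% of the counts numbered 1252 ± 59.8 in NT12, 553 ± 99.7 in CT12, 759 ± 91.4 in NT24 and 940 ± 42.6 in CT24 (SD, n = 3). The 100 most abundant genes held 20.4% ± 0.830 of the counts in NT12 and 30.4% ± 2.67 in CT12, against 26.5% ± 2.13 in NT24 and 22.2% ± 0.80 in CT24. Chilling thus went with a higher share at ZT12 and a lower share at ZT24. The number of genes with at least 1 count was 26784 ± 150 in NT12 and 25572 ± 478 in CT12, and it averaged 26296 in both groups at ZT24. In every one of these chilling comparisons except that of detected genes at ZT24 the 3 libraries of a group lay on the same side of the other 3. Each then had an exact permutation p of 0.1, two-sided, the smallest that 3 against 3 allows, and an adjusted p of 0.122 over 28 comparisons (Benjamini-Hochberg). The TMM factors were 1.33 ± 0.0206 in NT12, 0.787 ± 0.0767 in CT12, 0.986 ± 0.0451 in NT24 and 0.974 ± 0.0193 in CT24.

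Chilling at the end of the light period changed the transcripts of 11096 of the 24700 genes tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Of these, 6160 were higher and 4936 lower in CT12 than in NT12. Changes of at least 2-fold were found for 3502 higher and 3010 lower genes, and changes of at least 8-fold for 644 and 425. The median absolute log2 change of the called genes was 1.17. The identifiers with the largest rises were OsR498G0613110600.01 and OsR498G0917659900.01, for which the files give no name. OsR498G0613110600.01 went from 0.0407 ± 0.0573 CPM in NT12 to 19.3 ± 3.56 in CT12 (SD, n = 3), a log2 change of 8.78 (SE 0.56, edgeR adjusted p = 3.71e-07). It rested on 8 counts in NT12, 7 of them in replicate 2, and ranged from 8.19 to 10.82 when 1 library was left out. OsR498G0917659900.01 went from 0.109 ± 0.0927 to 41.7 ± 10.7 CPM, a log2 change of 8.55 (SE 0.59, edgeR adjusted p = 3.18e-06; 8.00 to 9.29 with 1 library left out). Among the genes that fell, OsR498G0101757700.01 went from 10.9 ± 4.08 to 0.157 ± 0.167 CPM, with a log2 change of -6.04 (SE 0.68, edgeR adjusted p = 2.76e-05; -7.42 to -5.59 with 1 library left out). For each of these 3 genes all libraries of the higher group lay above all of the lower group, as the rule for naming them required.

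The largest fitted fall at ZT12, that of OsR498G1018537100.01, rested on few libraries. Its level was 1.57, 31.5 and 214 CPM in the 3 NT12 libraries and 1.02, 0.0266 and 0.30 CPM in the CT12 libraries. The log2 change was -7.57 (SE 2.05, edgeR adjusted p = 0.0109), with -5.27 without NT12 replicate 3 and -9.02 without CT12 replicate 1. It was not called in 3 of 17 alternatives: limma-voom, limma-voom after cyclic loess, and the fit with the replicate number as a block. Adjusted p ranged from 0.000561 to 0.36 over the 17 alternatives.

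At ZT12 the direction of change went with abundance, here counted under TMM scaling unless stated. The median log2 change rose from genes under 1 CPM to genes over 100 CPM under each constant scaling. It went from -0.58 to 0.65 under TMM, from -0.87 to 0.36 under upper-quartile and from -1.32 to -0.11 under total-count scaling. A constant scaling moves all classes alike, so it keeps this order by construction. Of the 1901 genes averaging over 100 CPM, 1119 were higher and 140 lower after chilling, with a median log2 change of 0.65, against 622 and 652 and a median of -0.11 under total counts. Of the 4689 genes under 1 CPM, 358 were higher and 714 lower, with a median of -0.58. Total counts gave 229 higher and 1536 lower, and cyclic loess gave 638 and 337. Genes between 1 and 10 CPM had 1120 higher and 2333 lower members (1645 and 1436 after cyclic loess). Those between 10 and 100 CPM had 3563 and 1749, which turned to 2382 and 3223 under upper-quartile and to 1248 and 6103 under total-count scaling. Scaling by total counts moved the median of all genes from -0.02 to -0.77, and upper-quartile scaling moved it to -0.31. Cyclic loess, which removes such trends, gave genes over 100 CPM a median of 0.04, with 702 higher and 492 lower. The split of all called genes went from 6160 higher and 4936 lower under TMM to 4407 and 7794 under upper-quartile scaling and to 2624 and 13080 under total counts. Under all 4 of TMM, RLE, upper-quartile and total-count scaling, 2624 genes were called higher and 4847 lower. Between TMM and total counts, 532 genes were called with opposite signs.

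Chilling at the end of the dark period changed 10398 genes, 5419 higher and 4979 lower in CT24 than in NT24 (edgeR's quasi-likelihood test), a split that turned to 4616 and 5964 under upper-quartile scaling. Changes of at least 2-fold numbered 2839 higher and 2865 lower, and those of at least 8-fold 436 and 348. The median absolute log2 change of the called genes was 1.09. OsR498G0917659900.01, among the identifiers that rose most at ZT12, was again among those with the largest fitted rise. It had no count in the 3 NT24 libraries and 1.17 ± 0.368 CPM in CT24 (SD, n = 3), which was at least 53.4-fold higher (edgeR adjusted p = 0.000142). Its fitted rise therefore depends on the prior count, and its rank by size is not settled. OsR498G0100451500.01 had 3 counts over the NT24 libraries and 1421 over the CT24 libraries, a ratio of 442 with an exact 95% interval from 151 to 2150 that covers counting error only. Its level in CT24 was 9.73 ± 3.18 CPM, and its edgeR adjusted p was 1.33e-07. It was also called at ZT12, where it went from 1.29 ± 0.265 to 171 ± 13.3 CPM. OsR498G1120547200.01 fell from 7.30 ± 3.41 to 0.0435 ± 0.0586 CPM, a log2 change of -7.38 (SE 0.84, edgeR adjusted p = 4.22e-05). With 6 counts in CT24, it ranged from -9.21 to -6.78 when 1 library was left out.

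The fitted fall of OsR498G1018537100.01 at ZT24 rested largely on NT24 replicate 2, with 0.0863, 12.0 and 0.530 CPM in NT24 against 0, 0 and 0.0762 CPM in CT24. The log2 change was -7.15 (SE 2.61, edgeR adjusted p = 0.046), and it was not called in 8 of 16 alternatives. Without NT24 replicate 2 it was -3.39 (edgeR adjusted p = 0.399), and without CT24 replicate 1, 2 or 3 it was -6.61, -6.69 or -10.66 with edgeR adjusted p of 0.122, 0.12 and 0.118. The call was also lost under limma-voom, after cyclic loess, with the within-group factor and with the replicate number as a block. Adjusted p ranged from 0.00177 to 0.696 over the 16 alternatives.

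Abundance and direction were less closely tied at ZT24 than at ZT12 in the fitted values. Genes over 100 CPM had 731 higher and 349 lower members with a median log2 change of 0.19, and genes under 1 CPM had 343 and 571 with a median of -0.29. Cyclic loess, which removes such trends by construction, left 600 and 515 (median 0.00) over 100 CPM and 457 and 518 (median -0.03) under 1 CPM. Total-count scaling moved the median of all genes to -0.02, and upper-quartile scaling moved it to -0.12. Under all 4 scalings 4616 genes were called higher and 4736 lower. In the interaction, genes over 100 CPM had 166 members with a higher response at ZT24 and 665 with a lower response, which turned to 682 and 346 under total counts. Genes under 1 CPM had 172 and 121, which turned to 89 and 209 after cyclic loess.

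**Figure D2:**
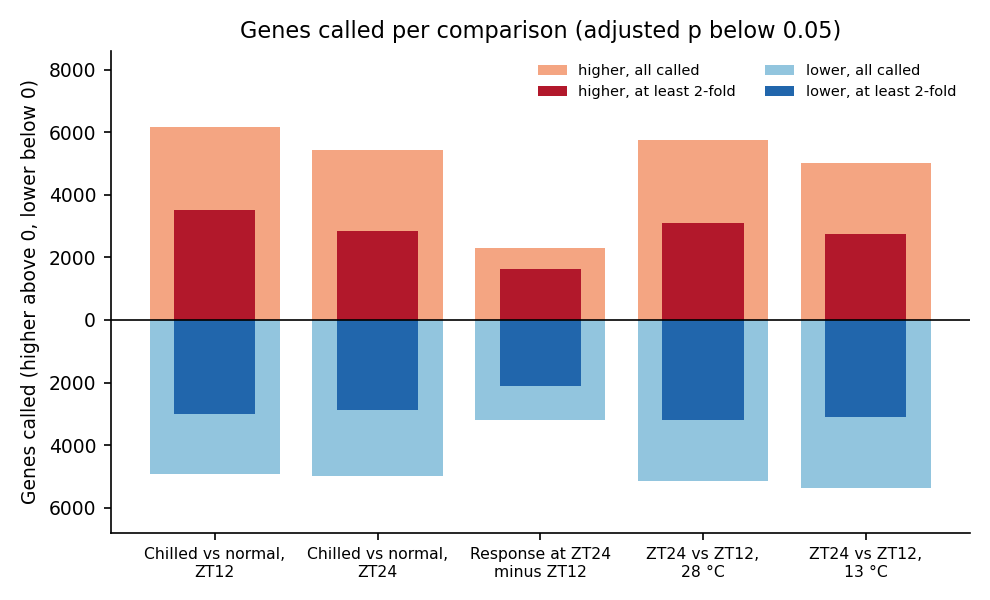
Bars give the number of genes called in each of the 5 comparisons, higher above 0 and lower below; the narrow dark bars count those of at least 2-fold. At ZT12 under TMM scaling 6160 genes were higher and 4936 lower after chilling, a split that turned to 4407 and 7794 under upper-quartile and 2624 and 13080 under total-count scaling. At ZT24 5419 were higher and 4979 lower, which turned to 4616 and 5964 under upper-quartile scaling. Between the times 5486 genes differed in response, with a split that turned under both scalings, as did those of time of day at normal temperature and under chilling.

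A large part of the chilling response was shared between the times of day. Genes that rose at both ZT12 and ZT24 numbered 3239, where independent lists would share 1351, and genes that fell at both numbered 2430, where independent lists would share 995. Of the 6613 genes called at both times, 5669 (85.7%) changed in the same direction and 944 in opposite directions, against 5497 and 1917 under total counts. At least 2-fold rises at both times were found for 1454 genes, and at least 2-fold falls for 1282. Of the 1454, 1077 had no called difference in response. Across genes, the log2 changes at ZT12 and ZT24 had Pearson's r = 0.479 and Spearman's rho = 0.475, with a jackknife SE of r over the 12 libraries of 0.0658. That SE pools the libraries without regard to the 4 groups. With 1 library left out, r was lower each time (0.401 to 0.477), so the SE is only a rough measure of spread. The 2 comparisons shared no library. Genes are not independent, so no p is given for this coefficient.

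**Figure D3:**
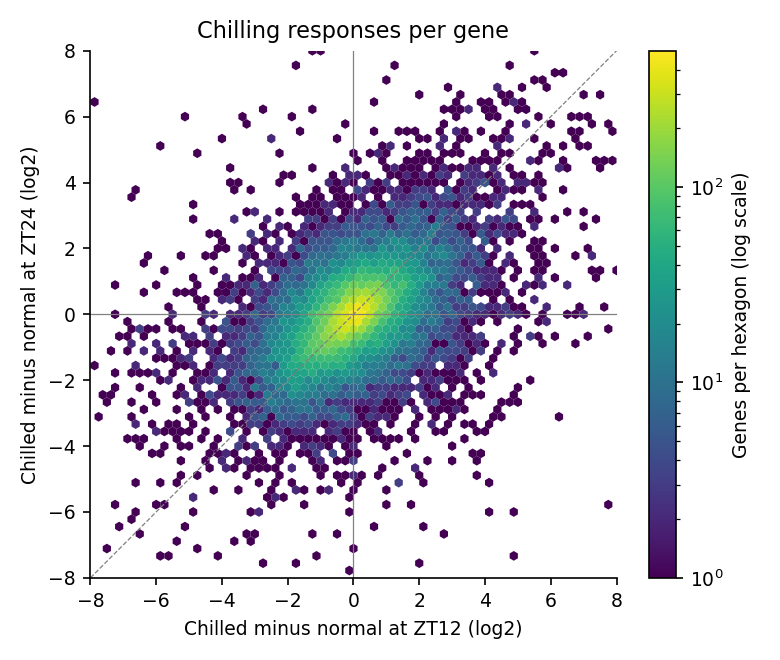
Each hexagon counts genes (colour, log scale) by their log2 change with chilling at ZT12 (horizontal) and at ZT24 (vertical); the dashed line marks equal changes, and 47 of 24700 genes lie beyond the axes at 8. Most genes called at both times lie in the quadrants of equal sign (5669 of 6613 under TMM; 5497 with equal and 1917 with opposite signs under total counts).

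For 5486 genes the response to chilling itself differed between ZT24 and ZT12 (interaction term, edgeR's quasi-likelihood test), with 2283 more positive and 3203 more negative at ZT24. The split turned to 3283 and 2446 under upper-quartile scaling and to 9279 and 1312 under total counts, which moved the median of all genes to 0.18 and 0.73. Under all 4 scalings 2275 genes were called more positive and 1309 more negative at ZT24. By class, 944 of the 5486 were called in opposite directions at the 2 times, of which 646 rose at ZT12 and fell at ZT24 and 298 did the reverse. A further 1126 changed in the same direction at both times but to different extents, 691 more at ZT12 and 435 more at ZT24. Another 1806 were called at ZT12 and not at ZT24 (1143 rose and 663 fell), and 1497 at ZT24 and not at ZT12 (858 rose and 639 fell). The remaining 113 were called at neither time. Opposite changes of at least 2-fold at both times were found for 275 genes.

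Abundant transcripts were among those with opposite responses. OsR498G0306485300.01 rose from 796 ± 56.9 to 22218 ± 3865 CPM with chilling at ZT12 and fell from 3307 ± 701 to 53.6 ± 4.82 CPM with chilling at ZT24 (SD, n = 3). Its log2 changes were 4.80 and -5.95, and the difference of -10.75 had an SE of 0.33 (edgeR adjusted p = 1.05e-08). OsR498G0307156300.01 rose from 0.0255 ± 0.0315 to 5.63 ± 1.32 CPM at ZT12 and fell from 39.1 ± 13.7 to 0.727 ± 0.332 CPM at ZT24. The difference in log2 change was -13.39 (SE 0.81, edgeR adjusted p = 8.12e-07), and -14.80 to -12.81 with 1 library left out. This gene was not abundant and rested on 5 counts over the NT12 libraries, 4 of them in replicate 2, so the size is poorly measured. In the other direction, OsR498G0612408600.01 fell from 238 ± 13.0 to 66.2 ± 5.15 CPM at ZT12, while at ZT24 it had 3 counts over the NT24 libraries and 682 over the CT24 libraries, a ratio of 212 (exact 95% interval 72.3 to 1030, counting error only). Its edgeR adjusted p for the difference was 3e-09. OsR498G0305340600.01 fell from 91.6 ± 17.3 to 5.35 ± 1.89 CPM at ZT12 and rose from 3.47 ± 0.424 to 15.4 ± 6.05 CPM at ZT24, a difference in log2 change of 6.25 (SE 0.47, edgeR adjusted p = 4.41e-06).

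**Figure D4:**
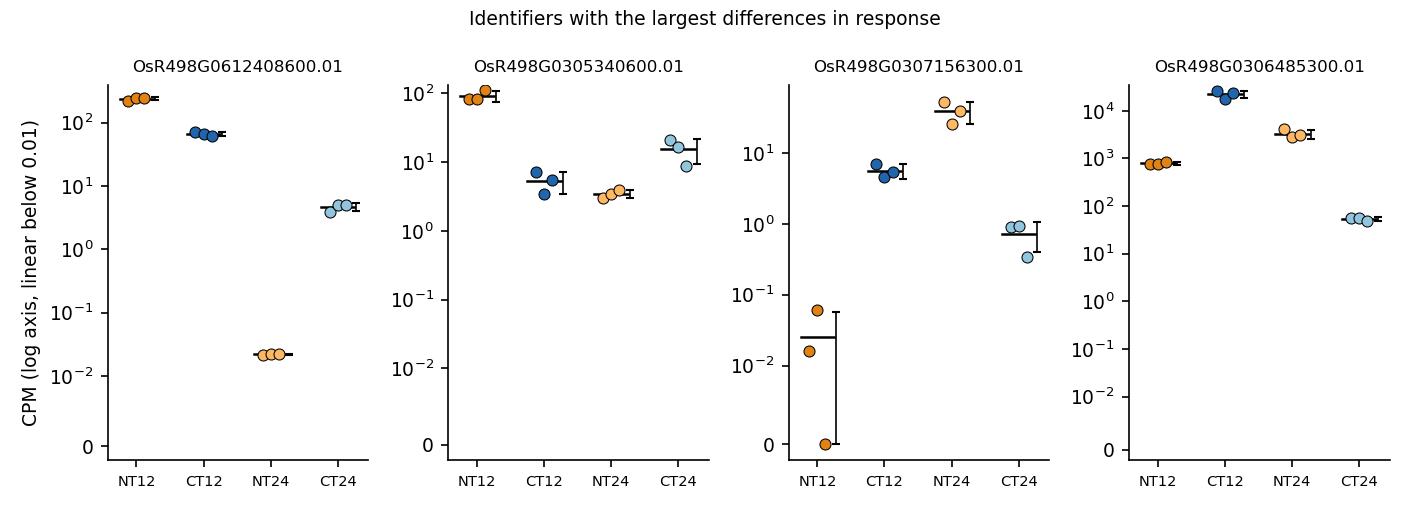
Points give the CPM of each library (vertical, log axis that is linear below 0.01) for the 4 identifiers with the largest differences in response, by group; horizontal lines are group means and bars are SD, ended at 0 where they would pass it. OsR498G0306485300.01 goes from 796 to 22218 CPM with chilling at ZT12 and from 3307 to 53.6 CPM at ZT24.

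At normal temperature, 10897 genes differed between the end of the night and the end of the day, which is the background of daily change against which the chilling responses stand. Of these, 5736 were higher at ZT24 and 5161 higher at ZT12 (edgeR's quasi-likelihood test), a split that turned to 4843 and 6012 under upper-quartile scaling. At least 2-fold differences numbered 3112 and 3205, and at least 8-fold differences 652 and 714. In total counts the split was 3100 and 8694, with the median of all genes moved to -0.39. Under all 4 scalings 3100 genes were called higher at ZT24 and 5161 higher at ZT12. For 3 genes all NT12 libraries had no count while each NT24 library had at least 100, and for 13 genes the reverse held. OsR498G0815333900.01 had no count in NT12 and 67.1 ± 11.2 CPM in NT24, at least 4340-fold higher (edgeR adjusted p = 5.05e-07). Novel00951 had no count in NT12 and 19.3 ± 14.7 CPM in NT24, at least 1250-fold higher (edgeR adjusted p = 1.02e-05), and at least 735-fold without NT24 replicate 1. OsR498G1221652500.01 went from 116 ± 18.2 CPM in NT12 to no count in NT24, at least 5340-fold lower (edgeR adjusted p = 2.93e-07). Novel00747 went from 68.2 ± 8.74 CPM to no count, at least 3120-fold lower (edgeR adjusted p = 1.84e-08).

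Under chilling, 10397 genes differed between ZT24 and ZT12, 5018 higher in CT24 and 5379 higher in CT12. At least 2-fold differences numbered 2731 and 3090, and at least 8-fold differences 441 and 645. Upper-quartile scaling turned the split to 5534 and 4992, and total-count scaling turned it to 7754 and 3534 and moved the median of all genes to 0.34. Under all 4 scalings 4930 genes were called higher in CT24 and 3534 higher in CT12. OsR498G0307059100.01 rose from 0.472 ± 0.507 CPM in CT12 to 328 ± 41.6 in CT24, a log2 difference of 9.39 (SE 0.61, edgeR adjusted p = 4.12e-07; 8.88 to 10.76 with 1 library left out). OsR498G0815333900.01, absent from the counts in NT12, went from 0.197 ± 0.191 to 41.0 ± 2.07 CPM, a log2 difference of 7.75 (SE 0.54, edgeR adjusted p = 3.43e-06; 7.11 to 8.64 with 1 library left out). OsR498G0101502300.01 fell from 282 ± 51.6 to 0.0276 ± 0.0308 CPM, a log2 difference of -13.21 (edgeR adjusted p = 1.34e-07), and -14.42 to -12.62 with 1 library left out. It rested on 4 counts over the CT24 libraries, so its size is poorly measured. OsR498G0102419700.01 went from 20.03 ± 2.15 CPM to no count, at least 983-fold lower (edgeR adjusted p = 1.56e-07).

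Much of the difference between ZT24 and ZT12 was present at both temperatures. Chilled seedlings had spent only the last 4 h before harvest at 13 °C. Differences that arose earlier, at 28 °C, therefore cannot be told apart from those that arose under chilling. Of the 6788 genes called between ZT24 and ZT12 at both temperatures, 6165 (90.8%) differed in the same direction, 3043 higher at ZT24 and 3122 higher at ZT12. Under total counts 5068 differed in the same direction and 1446 in opposite directions, against 623 under TMM. Independent lists would share 1165 and 1124. In the opposite direction, 442 genes were higher at ZT24 under normal temperature and higher at ZT12 under chilling, and 181 did the reverse. The genes higher at ZT24 at normal temperature had a median log2 difference of 1.09 there and 0.56 under chilling. Those higher at ZT12 had medians of -1.25 and -0.80. With genes lacking counts in a group set to their bounds, the medians were 1.09, 0.56, -1.25 and -0.79. Genes selected for a difference at normal temperature are drawn toward larger values there, and genes selected under chilling showed the reverse, with medians of 1.09 under chilling and 0.77 at normal temperature, and of -1.15 and -0.77. The SD over all genes was 1.56 at normal temperature and 1.45 under chilling. Of the 10897 genes called at normal temperature, 4018 had a called interaction. In 1921 of these the difference was smaller under chilling with the same sign, in 577 it was larger, and in 1520 the sign differed. Across genes the log2 differences at the 2 temperatures, which shared no library, had Pearson's r = 0.560 and Spearman's rho = 0.524.

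**Figure D5:**
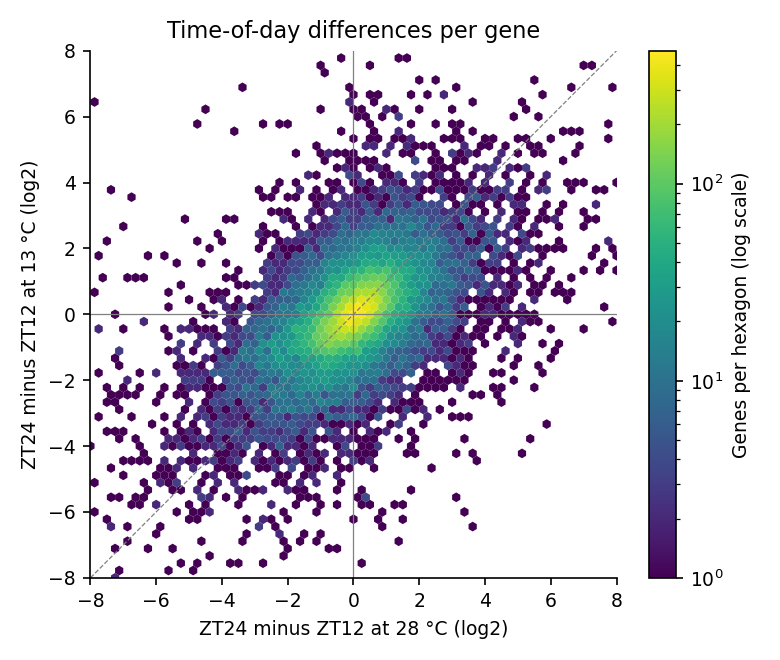
Each hexagon counts genes (colour, log scale) by their log2 difference between ZT24 and ZT12 at 28 °C (horizontal) and after 4 h at 13 °C (vertical). The dashed line marks equal differences, and 111 of 24700 genes lie beyond the axes at 8. Of the genes called at both temperatures 6165 of 6788 lie in the quadrants of equal sign under TMM (5068 with equal and 1446 with opposite signs under total counts).

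Genes numbered in the series that includes Novel00951 and Novel00747 lay below the other genes in their response to chilling. Under TMM they were lower more often and higher less often than other genes. At ZT12 the share called lower was about that of other genes after cyclic loess (270 of 1350 against 4493 of 23350) and under total counts (711 against 12369), while a smaller share was higher (196 against 5555, and 80 against 2544). Their median stayed below, at -1.34 against -0.75 under total counts, where a constant shift keeps the gap by construction. The group took 2.22% ± 0.121 of the counts in NT12 and 1.42% ± 0.0533 in CT12, and 1.55% ± 0.0753 in NT24 and 1.21% ± 0.0158 in CT24 (SD, n = 3). At both times the exact permutation p was 0.1, the smallest possible (adjusted p 0.122). Of the 1350 tested, 162 were higher and 389 lower at ZT12 (114 and 501 under upper-quartile and 80 and 711 under total-count scaling), and 142 were higher and 397 lower at ZT24. Among the other 23350 genes, 25.7% were higher and 19.5% lower at ZT12, and 22.6% and 19.6% at ZT24. The median log2 change of the group was -0.60 at ZT12 and -0.53 at ZT24, against 0.00 and 0.01 for other genes, and -0.59 and -0.53 with genes lacking counts set to their bounds. Limma's camera test, which sets a group against all other genes, gave an adjusted p of 0.00068 at each time over the 5 comparisons, and an adjusted p of 0.00392 with an estimated correlation. Limma's fry test, which asks whether the group moves 1 way on balance, gave adjusted p of 1.54e-06 and 1.22e-06. In the other 3 comparisons camera's adjusted p lay between 0.634 and 0.87, while fry's was 0.857 for the interaction, 0.00505 for time of day at normal temperature and 0.0396 under chilling. After cyclic loess the medians at ZT12 and ZT24 were -0.26 and -0.39, against -0.01 and 0.03 for other genes, and at ZT24 383 of the 1350 and 4969 of the 23350 were lower. The group was defined after the identifiers were seen, and if it was assembled from these libraries it is not independent evidence of a direction.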

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

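The tests with the within-group factor and its axis, with cyclic loess and with constant shifts of the scaling, and those on the shared axis and on the Novel00951-type genes, were chosen only after the pattern they bear on had been seen.

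The response to chilling differed between ZT24 and ZT12 for 5486 genes, by a test of the difference itself. Scaling of the libraries was argued against as the whole cause, since none of 9 constant shifts of the CT24 libraries, between -1 and 1 on the log2 scale, lowered the number called. The lowest was 5486, at no shift. TMM had already centred the difference (median -0.005 over all genes), so a minimum near no shift was close to fixed in advance. The shifts thus add little to the count under TMM itself. A trend with gene abundance was argued against by 5314 genes called after cyclic loess. Group means displaced along the within-group axis were argued against as the whole cause, since over the 5486 genes the difference and the axis loading had r = 0.115 (from -0.0485 to 0.143 with the loadings of single groups), whereas the 6934 genes called with this factor as a covariate decide nothing, because its scores sum to 0 in every group. In 1 of 60 splits drawn from 200, the real one, as many genes were called, and the highest other split called 3286, but these splits do not settle chance for this difference: mixed ones move the chilling effects into the spread between libraries, and exchanging all labels at ZT24 alone, a split not drawn that tests the sum of the 2 responses, called 13017. A biological difference between the times of day stays a hypothesis, and a part of light, whose state during chilling is not stated in the labels, stays open, untested.

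Genes whose difference in response (ZT24 minus ZT12) was itself called are listed here as log2 values. Besides OsR498G0307156300.01 (-13.39), OsR498G0306485300.01 (-10.75), OsR498G0612408600.01 (9.42) and OsR498G0305340600.01 (6.25), the difference was -7.99 for OsR498G0613110600.01, which had 8 counts in NT12 and a called rise at ZT12, and went from 9.77 to 16.92 CPM at ZT24 (edgeR adjusted p = 0.097 there). OsR498G0101757700.01 had a difference of 3.36, with falls called at both times. OsR498G0307059100.01 had a difference of 2.56, also with falls called at both times. For OsR498G0815333900.01 (-6.92), Novel00951 (-7.48) and Novel00747 (4.35), as for OsR498G0612408600.01, a group had no count or 1 count per library, so the fitted value depends on the prior count and is no measure of size. OsR498G0307156300.01 had 5 counts over the NT12 libraries, so its value too is a weak measure of size.

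Deviations of libraries from their group means followed 1 axis shared by libraries of different groups, which held 38.1% of the variance of those deviations. CT12 replicate 2 had the highest score (0.580) and CT12 replicate 1 the lowest (-0.403). A harvest time differing within groups stays open: in 0 of the 4 groups did the axis correlate with the daily difference across genes at an absolute r of 0.3 or more (r from -0.0685 to 0.0741), but that difference spans 12 h and need not follow the slope at either time, so the low r set as counting against it excludes nothing. Sequencing depth stays open: over the 12 libraries r was 0.453 (exact within-group permutation p = 0.147) and rho 0.476 (exact p = 0.174), with r = 0.422 without the 2 libraries farthest from the median depth, and 12 libraries are too few to settle it. A trend with gene abundance stays open too, with rho across genes of -0.0362 in NT12, -0.0794 in NT24, -0.162 in CT24 and -0.184 in CT12; no biological explanation was tested.

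Genes of the Novel00951 type had lower median changes than other genes at both times, -0.60 at ZT12 and -0.53 at ZT24. Their lower abundance was argued against as the whole cause: of 10000 lists of other genes matched on abundance, 0 had a median as low at either time, and the lowest were -0.42 and -0.23. Matched lists still had medians of -0.27 and -0.09, so abundance may account for part. After cyclic loess 270 of the 1350 were lower at ZT12, about the share of other genes (4493 of 23350), and 196 higher (5555 of other genes), with a median of -0.26 against -0.01, and at ZT24 383 were lower (4969 of other genes), with a median of -0.39 against 0.03. How these identifiers were built, including whether from the normal-temperature libraries, is not given in the sources used here, and stays open; no biological explanation was tested.

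For comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. Fits of only those 6 libraries called 9497 genes in the real split and at most 1 in the others for CT12 against NT12, and 10909 and at most 0 for CT24 against NT24. For NT24 against NT12 the numbers were 11705 and 1, and for CT24 against CT12 they were 8310 and 0. In each of these 4 comparisons 1 of 10 splits, the real one, gave as many genes. Every other split mixed the 2 groups compared, which moves their difference into the spread between libraries. Few calls there follow from the mixing, so these numbers do not settle chance.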

How the results depend on the processing

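Total counts, the within-group factor and cyclic loess were chosen as alternatives after the data had been seen. Of the counts of genes per comparison and the overlap under all alternatives, 115 stayed within 1.5 times the value reported, 1 was higher and 9 were lower. The higher one was the interaction in total counts (10591), where the median of all genes moved to 0.73. Like numbers can hide a change of members. Of the genes called for chilling at ZT12, 72.9% were still called, in either direction, under total counts. The share was 76.1% after cyclic loess, 84.2% under upper-quartile scaling and 99.2% under RLE. For the interaction the shares were 65.6%, 82.1%, 86.2% and 98.9%, in the same order. At an adjusted p below 0.01, 6907 genes were called at ZT24 by chilling, 3025 in the interaction and 3567 in the overlap. Against a fold of 1.5, the counts were 6012 for chilling at ZT12, 5050 at ZT24, 2633 for the interaction, 6124 for time of day at normal temperature, 5360 under chilling and 2447 for the overlap. Both settings are stricter by construction.

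Leaving out 1 library at a time gave 9522 to 11867 genes for chilling at ZT12, 8599 to 9341 at ZT24, 4260 to 7124 for the interaction, 9208 to 9856 for time of day at normal temperature, 8722 to 11725 under chilling and 4849 to 6034 for the overlap. The highest value came without CT12 replicate 2 for chilling at ZT12, the interaction, time of day under chilling and the overlap. This library differed most from the others of its group. Its chi-square statistics per gene were 138 and 139, against 32.3 between CT12 replicates 1 and 3. In the other groups this statistic was at most 89.5. The TMM factor of CT12 replicate 2 was 0.875, against 0.733 and 0.753 in CT12 replicates 1 and 3. DESeq2 called 12179, 11559 and 6821 genes for chilling at ZT12, chilling at ZT24 and the interaction. Of the values of single genes, 348 kept direction and call and 11 kept direction only, all 11 for OsR498G1018537100.01; none reversed. The correlation of responses moved by more than its jackknife SE, a rough measure here, without the filter (0.364) and without CT12 replicate 2 (0.401). The cause was not tested.

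The replicate numbers did not pair the libraries: of 18 same-numbered pairs in different groups, 4 had deviations correlated above 0.1 (range -0.444 to 0.285), and 0 of 12 libraries correlated best with their own number. With the replicate block 10157 and 9361 genes were called for chilling at ZT12 and ZT24, 4521 for the interaction, 10066 and 9401 for time of day and 5012 for the overlap. The alternatives for gene list tests were not run, since no identifier could be matched to a list. Depth limits changes near the floor, and at 3 libraries per group 4 of 100 simulated 2-fold interactions on 24288 genes were recovered. That simulation changed far fewer genes than were called here, which makes the cutoff stricter, so this share may understate recovery in these data.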

Other observations

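The set of covariances and the order of identifiers were tested as hypotheses, and the removal of the abundance trend was chosen as a test only after abundant genes had been seen to rise more often.

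Some of the most abundant transcripts carried large shares of the libraries and moved with time or temperature. Chosen after its values were seen, OsR498G1120774600.01 held 0.228% ± 0.0414 of the counts in NT12, 0.293% ± 0.0452 in CT12, 3.43% ± 0.496 in NT24 and 1.73% ± 0.104 in CT24 (SD, n = 3). OsR498G0714482300.01, chosen in the same way, held 0.928% ± 0.0828 in NT12 and 0.882% ± 0.0795 in CT12, against 7.14e-05% ± 6.76e-05 in NT24 and 0.00119% ± 0.000401 in CT24.

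Chilling at ZT24 may have kept a part of expression nearer to its state at ZT12, though not expression as a whole. Across genes, the log2 response at ZT24 and the normal-temperature difference between ZT24 and ZT12 had a covariance of -0.636. These comparisons share the NT24 libraries. In 50 simulations without any effect, covariances ran from -0.12 to -0.108 with a mean of -0.114, so that the difference was -0.522. The simulations drew each gene independently and held no response to chilling or time, so they cover noise from the shared libraries only. A response unrelated to time of day was not simulated, so lying below the range does not decide for the hypothesis. Leaving out 1 library at a time gave -0.781 to -0.606, and r was -0.382 against a simulated -0.504. The controls could not be split with 2 libraries on each side, so part of the relation may still come from the shared libraries. The part of light in either state was not tested. Over all tested genes, r of log2 CPM with the NT12 libraries was alike for CT24 libraries (0.847 to 0.871) and NT24 libraries (0.846 to 0.875). CT24 libraries lay nearer to NT12 than NT24 libraries did on the first principal component, and farther from it on the second.

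A matching hypothesis, that chilling at ZT12 moved expression toward its ZT24 state, was met by a smaller value. The covariance of the ZT12 response with the same daily difference was 0.301, above the simulated 0.105 to 0.119 from the shared NT12 libraries (mean 0.110, difference 0.191), with 0.295 to 0.397 when 1 library was left out and r = 0.163 against a simulated 0.485. These simulations too held no response, so lying above their range does not decide for the hypothesis. Both differences rose with abundance (rho 0.348 and 0.125), and without a trend on abundance the covariance was 0.231, still above the simulated range. Such a trend may account for part of the covariance, but not for the 0.231 left after its removal. On the first principal component, by contrast, the CT12 libraries lay farther from NT24 than the NT12 libraries did. Over all tested genes, r of log2 CPM with the NT24 libraries was also lower for CT12 libraries (0.797 to 0.825) than for NT12 libraries (0.846 to 0.875). These values argue against a movement of expression as a whole toward the ZT24 state. The positive sign thus held for the sum over genes, and neither for the axis of largest variance nor for the likeness of the libraries.

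Genes with consecutive identifiers may respond to chilling together. Over 23337 pairs next to each other in identifier order, rho of the log2 response was 0.153 at ZT12 and 0.121 at ZT24, where the highest of 1000 random orders gave 0.0191 and 0.0247. The coefficient was 0.0689 and 0.0535 at a gap of 2, and 0.0284 and 0.0227 at a gap of 5. Where both members were called, 62.3% and 60.3% had the same sign, against 51.0% and 50.3% if independent. Whether such identifiers are neighbours in the genome, or copies that share reads, is not given in the sources used here, and reads shared between copies stay an open, untested source.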
